A study of Cottus with 7 samples.

How the data were processed

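The series holds 7 arrays of a custom design, 1 per amount of a single labelled pool. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1. Per the file headers, the deposited intensity of each spot came from a 1-colour Cy3 scan, was background-subtracted and detrended within the array, and was not scaled between arrays. The value table of the series held the same intensity values, with 0 difference from the scanner output, so its scale was linear and nothing was centred; direction did not arise with 1 colour. Its medians were 79.5, 178.3, 328.3, 554.0, 1033, 1750 and 3578 from the lowest to the highest amount.

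Amounts came from the titles. All 7 arrays shared a slide and scan, and slide row was read from the array position. Of 15744 features, 536 control spots were left out of probe results and treated apart. Spots marked as outliers by the scanner software were dropped, from 6 to 22 per array, and the log2 processed signals of the remaining spots were averaged per probe. A probe counted as measured where at least 50% of its spots were well above background and it was not saturated; 11533 probes were measured on all 7 arrays.

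Slopes were fitted on log2 amount with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) without scaling between arrays, since scaling would remove the change under study. Separate tests asked for a slope other than 0, a slope other than 1, a slope relative to the array after subtraction of its 75th percentile, and a squared term of centred log2 amount. The Benjamini-Hochberg threshold was 0.05. Because no scaling was applied, array-wide deviations are shared by all probes and p-values of the unscaled tests are too small; those p-values are not printed. In these unscaled fits the moderation gave every probe the same SE, 0.0297 for slopes and 0.0153 for bends. Their calls therefore followed the size of the coefficient and not the scatter of the single probe. With no replicate arrays, the p-values measure scatter around a line only. A power law and a Langmuir curve, each with 2 parameters, were fitted to log2 signal by least squares, the latter over 701 values of its constant.

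Relations of array summaries with amount used Pearson's and Spearman's coefficients with exact two-sided permutation over 5040 orders. Relations across probes used ranks, with cubic terms for the quantities held fixed and 100000 resamples. Folding energies of the probe sequences came from ViennaRNA 2.7.2 with DNA parameters at 65 °C and, beside it, 37 °C; neither temperature was given in the sources used here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

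The groups, tests, most alternatives and the rule for named probes were fixed before the data were examined. That rule took the 2 probes with the largest positive and the 2 with the largest negative relative slope past the threshold. Alternatives changed the background correction, the probe filter, the scaling, the variance model, slide row as a block and the arrays included. The normexp correction added an offset of 50 intensity units to every spot, and the fits without subtraction kept the background in the signal. Either addition flattens the slopes of dim probes and bends them upwards. Shifts that way under these settings were therefore partly fixed in advance. Fits without variance moderation were added after the data had been seen. Tests of gene lists were not run, since the files give no gene names. The procedures were tested on simulated data with 200 changed probes among 11533: changes of 0.1 in slope were recovered in 93% of cases for the test against 0, 89% for the test against 1 and 88% for the relative test, and bends of 0.02 and 0.06 in 17% and 75%. These simulations drew noise for each probe apart, of the size left after scaling, and held no array-wide deviations. For the unscaled tests they therefore do not give the recovery in the real arrays.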

Results

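The series measured how the signal of a custom expression array followed the amount of target put on it. A single pool of Cy3-labelled cRNA, mixed in equal molar shares from whole sculpins of Cottus rhenanus, Cottus perifretum and an invasive hybrid lineage, was hybridised at 75, 150, 300, 600, 1200, 2400 and 4800 ng. The recommended amount was 600 ng, and the highest was 8 times that. Each amount had 1 array and no replicate, so errors below come from the scatter of the 7 arrays around fitted lines, and the number of arrays limits the precision. The array carried 13329 probes of 60 bases for 13305 assembled transcript contigs, on 15208 spots. The files do not pair the contigs with gene names, so probes are given by identifier. All 7 arrays lay on 1 slide, with 75, 150 and 300 ng in slide row 1 and the 4 higher amounts in slide row 2, so that slide row and amount overlapped. Within each row, amount also rose with slide column. Fits within a row or with row as a block therefore do not separate amount from slide position.

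The first question was whether the arrays brightened in step with the target. The signal rose with every doubling, by somewhat less than the amount over the whole range. The median processed signal of the 11533 probes measured on all 7 arrays rose from 127.2 at 75 ng to 893.2 at 600 ng and 5747 at 4800 ng, a 45.2-fold rise over a 64-fold range of amount. The log-log slope of the array medians was 0.89 ± 0.021 (SE, n = 7), with a 95% interval of 0.83 to 0.94, where 1 would be proportional. Pearson's r was 0.999 and Spearman's rho was 1, each with an exact two-sided permutation p of 0.000397, the smallest that 7 amounts allow (0.000662 after Benjamini-Hochberg adjustment over 10 relations of array summaries with amount). Without the 75 and 4800 ng arrays r was 1.00. With slide row as a block the slope was 0.92 ± 0.0426, with a 95% interval of 0.80 to 1.04 that included 1, so the departure from proportionality was not kept apart from slide row. It was 1.02 ± 0.0766 within row 1 (3 arrays) and 0.88 ± 0.0349 within row 2 (4 arrays), with intervals that also included 1.

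The steps between neighbouring amounts were uneven. A doubling raised the median by 1.15 on the log2 scale from 75 to 150 ng, 0.89 from 150 to 300 ng, 0.77 from 300 to 600 ng, 0.90 from 600 to 1200 ng, 0.76 from 1200 to 2400 ng and 1.02 from 2400 to 4800 ng. With no replicate arrays, the spread between arrays of the same amount was not measured. Within an array, the SD over spots of a probe had a median of 0.0473 to 0.0762 on the log2 scale for probes with 10 spots, and was 0.0707 to 0.162 when pooled over probes with 2 spots.

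**Figure D1:**
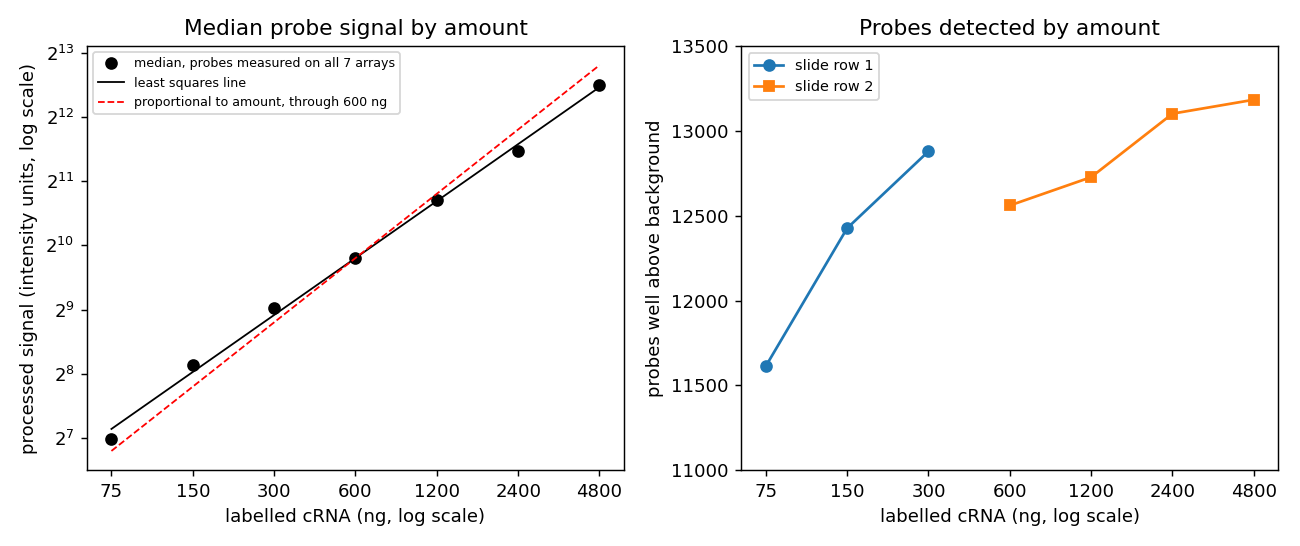
Left, median processed signal (intensity units, log scale) of 11533 probes against labelled cRNA (ng, log scale), with the least squares line of slope 0.89 and a broken line for proportional signal through 600 ng. Right, number of probes well above background against amount, by slide row; the vertical axis does not start at 0, and the count was 12879 at 300 ng and 12560 at 600 ng.

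More target also brought more probes into view. Probes well above background numbered 11613 at 75 ng, 12426 at 150 ng, 12879 at 300 ng, 12560 at 600 ng, 12727 at 1200 ng, 13101 at 2400 ng and 13183 at 4800 ng, the last being 98.9% of the 13329 probes. Only 121 probes stayed below that limit on all 7 arrays. The count rose with log2 amount (Pearson's r = 0.862, exact permutation p = 0.00675, adjusted 0.00964; Spearman's rho = 0.893, exact permutation p = 0.0123, adjusted 0.0154), and r was 0.715 without the 75 and 4800 ng arrays. The single fall, from 300 to 600 ng, crossed from slide row 1 to row 2. The SD of the mean signal of the negative control spots rose there from 1.56 to 9.68 intensity units, with spots marked as outliers kept. Without them, the SD of their log2 processed signal was 0.146 at 300 ng and 0.142 at 600 ng. A generally noisier background in row 2 was therefore not shown. The count gained 633 probes per doubling within row 1 and 224 within row 2. At the upper end, 0 probes were marked as saturated on any array, and the brightest spot reached 65.2% of the scanner's saturation value.

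Single probes behaved much like the array as a whole. Of the 11533 probes, 11528 rose with amount and 1 fell in limma's test (Benjamini-Hochberg adjusted p under 0.05). The median probe had a slope of 0.89, the middle 50% of probes lay between 0.84 and 0.92, and 83.3% had a slope from 0.8 to 1. A slope of 0.89 means that a doubling of target raised the signal 1.85-fold. The array-wide deviations enter every probe alike, so these counts are not 11533 independent results.

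Without regard to slide row, most probes rose by less than the target did. In limma's test against a slope of 1, 10169 probes lay below 1 and 3 above it. With slide row as a block, the counts fell to 2132 below and 6 above. When all slopes were simulated at 1 with array-wide deviations of the observed size, the median count was 37 probes, and 1 of 100 simulations reached the observed number. Those deviations were drawn independently for each array around a fitted line. The simulations therefore cannot decide about an offset between slide rows or another deviation that follows amount.

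Probes also differed from each other in how steeply they responded. After scaling each array to its 75th percentile, 3556 probes rose more steeply than the array and 3187 less steeply (limma, adjusted p under 0.05). The split moved with the background treatment, to 917 steeper and 6695 shallower after normexp correction and 1236 and 5754 without background subtraction. Both settings leave an added signal in every spot, which by itself makes dim probes shallower. The split moved the other way with the scaling, to 4777 and 2356 after quantile normalisation. With slide row as a block the counts were 1168 and 1482. In pairs of probes with identical sequence but different names, the slopes were close, with a median difference of 0.0086 over 27 pairs against 0.0544 when partners were shuffled (permutation p = 1e-05, the smallest that 100000 resamples give).

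Slope varied with brightness. Probes were ranked by mean signal into 10 classes of equal size. The dimmest class had a median slope of 0.81 and the brightest class 0.83, while the class with a mean log2 signal between 9.80 and 10.57 had 0.91. In the brightest class the last doubling raised the median signal by 0.81 on the log2 scale, against 1.05 in that middle class. In the dimmest class the last doubling gave 1.02, but the first gave only 0.87, against 1.19 in the middle class. Only probes measured on every array were included. That filter drops dim probes with a low reading at the lowest amount, which can by itself flatten the dimmest class. Its low slope was therefore not shown to be a property of dim probes. The brightest class held 713 probes shallower and 49 steeper than the array, out of 1154. Slopes under 0.5 were found in 259 probes, 2.25% of those measured, of which 130 were in the brightest class. The number was 1507 (13.1%) after normexp correction and 645 (5.59%) without background subtraction.

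**Figure D2:**
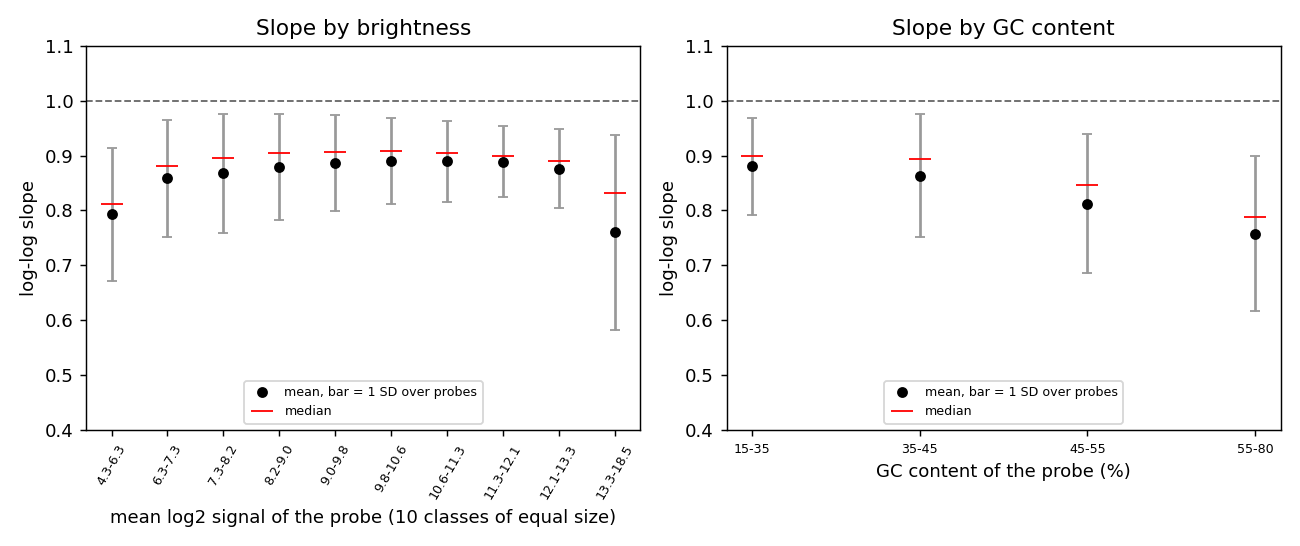
Log-log slope of signal on amount for 11533 probes, by 10 classes of mean log2 signal (left) and by GC content in percent (right). Points are means, bars 1 SD over probes, red marks medians and the broken line a slope of 1; medians were 0.81 in the dimmest and 0.83 in the brightest class, and 0.79 above 55% GC.

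Slope also fell with the GC content of the probe. The median was 0.90 in 3119 probes of at most 35% GC, 0.89 in 6631 probes up to 45%, 0.85 in 1576 probes up to 55% and 0.79 in 207 probes above that. Across probes, which are not independent replicates, the rank correlation of GC with slope was -0.211 and -0.209 with mean signal held fixed (permutation p = 1e-05 for each, the smallest that 100000 resamples give; adjusted 1.25e-05 over 5 relations). It was negative in all 10 classes of brightness, from -0.358 to -0.0204.

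Bending of the log-log relation was less certain. limma called 551 probes, 404 bending down and 147 up, by the size of the bend alone, since moderation gave every probe the same SE of 0.0153. Of those bending down 317 were in the brightest class, and of those bending up 130 were in the dimmest class, near background. The filter for measured probes can add to upward bends in that class, which was not tested. Without variance moderation 0 probes passed, and 1071 had an unadjusted p under 0.05, where chance alone would give 577 of 11533; with moderation 1380 did. The balance of directions turned after normexp correction, with 876 down and 4068 up, and without background subtraction, with 690 down and 2266 up. Those settings leave an added signal in every spot, which by itself bends dim probes upwards. The balance also turned when the 75 ng array was left out, with 185 down and 290 up. After scaling to the 75th percentile it was nearly even, with 520 down and 428 up.

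A power law described 77.5% of probes better than a Langmuir curve, which levels off at a maximum signal, when both had 2 parameters. The median root mean square deviation was 0.111 and 0.128 on the log2 scale. In the brightest class the Langmuir curve was closer for 76.6% of 1154 probes. The share for the power law was 20.8% without the 4800 ng array and 96.0% without the 75 ng array, so the preference rested on the ends of the range.

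The probes at the extremes of relative slope were named by a fixed rule. The steepest was CUST_4040_PI425378893 for contig13324, whose signal went from 25.3 at 75 ng to 3644 at 4800 ng, with a relative slope of 0.30 ± 0.0298 (SE, n = 7; limma adjusted p = 0.000268). After normexp correction its relative slope was 0.07 and its limma adjusted p was 0.413, but that correction adds 50 units to every spot. CUST_978_PI425378893 for contig24462 had a relative slope of 0.18 ± 0.0628 (limma adjusted p = 0.042). It read 1990 at 600 ng and 8784 at 1200 ng, and it missed the threshold when any 1 array other than the 600 ng array was left out, with relative slopes from 0.16 to 0.20. With slide row as a block it also missed the threshold, at a relative slope of 0.31 (limma adjusted p = 0.113). The shallowest was CUST_3010_PI425378893 for contig00176, at a relative slope of -0.96 ± 0.0307 (limma adjusted p = 3.34e-06). Its signal was 246.1 at 75 ng, 284.5 at 600 ng and 180.6 at 4800 ng. It was the probe called as falling, a call absent after normexp correction, without background subtraction, without variance moderation and without the 4800 ng array. CUST_1381_PI425378893 for contig14403 had a relative slope of -0.87 ± 0.0831 (limma adjusted p = 0.000225), with 63.4 at 75 ng, 32.1 at 300 ng and 61.1 at 4800 ng.

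**Figure D3:**
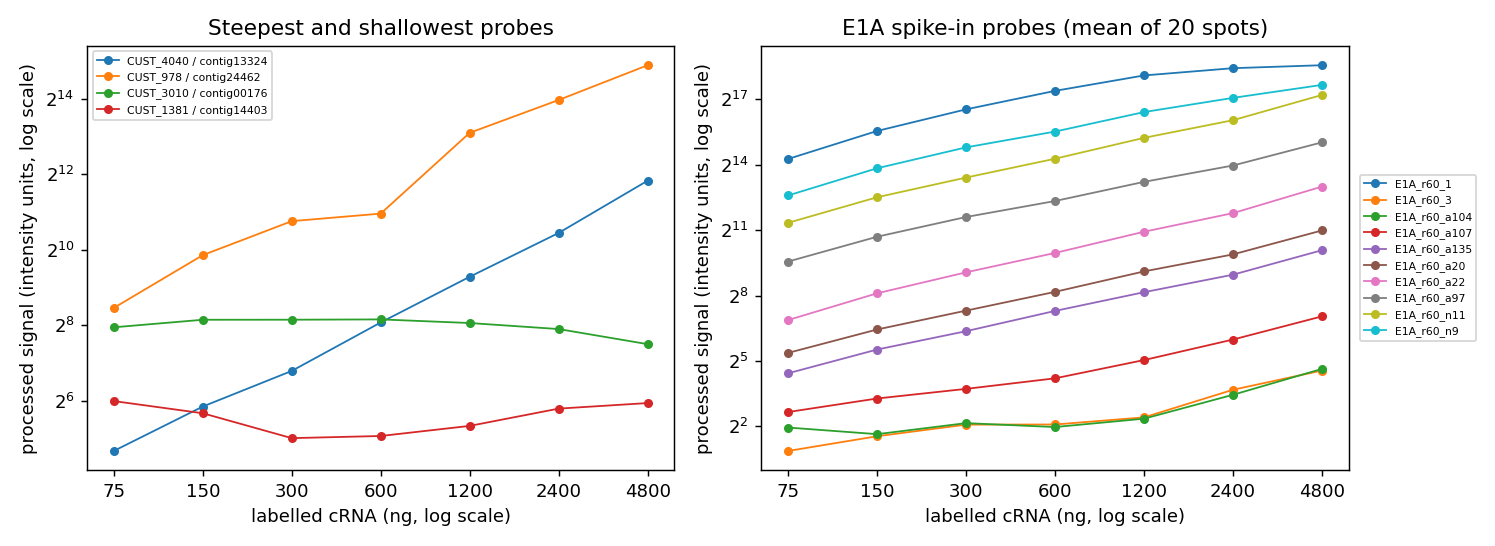
Processed signal (intensity units, log scale) against labelled cRNA (ng, log scale). Left, the 2 steepest and 2 shallowest probes, 1 spot each per array; right, the 10 E1A spike-in probes, means of 20 spots, where the brightest went from 19740 to 389000 while the amount rose 64-fold.

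Control spots were set against the same amounts. The 200 spots of the 10 E1A spike-in probes rose with a slope of 0.79 ± 0.0144 (SE, n = 7; exact permutation p = 0.000397 for r = 0.999 and rho = 1; r = 0.999 without the 75 and 4800 ng arrays; adjusted 0.000662). That mean includes 3 probes not above background on all arrays. The other 7 had a mean slope of 0.88 (SD 0.0864 over probes), from 0.72 in the brightest probe to 0.99. The bright corner spots, 14 per array, rose 13.6-fold with a slope of 0.62 ± 0.0241 (r = 0.996 and rho = 1, exact permutation p = 0.000397, adjusted 0.000662; r = 0.998 without those arrays). The 77 negative control spots stayed near the floor, at 1.44 at 75 ng and 4.10 at 4800 ng. Their mean log2 signal was 0.53 at 300 ng and 1.72 at 600 ng, across the slide rows (slope 0.32 ± 0.0762; r = 0.881, exact permutation p = 0.0194, adjusted 0.0206; rho = 0.857, exact permutation p = 0.0238, adjusted 0.0264; r = 0.872 without those arrays).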

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

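Control kinds not described above were set against the negative control spots after their values had been seen. They are among the 10 relations of array summaries with amount. The limit was the mean of those spots plus 3 SD, 2.38 on the log2 scale at 4800 ng. It is a low limit, since their processed signal lay near the floor, with an SD of 0.116 on the log2 scale. The SD of their mean signal before background subtraction, outliers kept, was 5.95 intensity units. Spots named DCP reached 11.55 at 4800 ng, with a slope of 0.81 on log2 amount. Spots named ETG reached a mean of 3.31 (SD 1.28 over 78 spots), with a slope of 0.41, and 24.4% of them were well above background. The eQC spots, which the files class as negative for hybridisation, reached 3.90 with a slope of 0.48, and 50% of their 24 spots were well above background at 4800 ng against 0% at 75 ng. Spots named RC, at 2.06, and the dark corner spots, at 2.13, stayed under the limit at 4800 ng.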

How the results depend on the processing

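The fits without variance moderation were chosen only after the data had been seen. No paired analysis was possible because each amount had 1 array and the replicate number is only a name. The positive relation of median signal and of detected probes with amount held under every alternative with a test; leaving out 1 array gave median slopes of 0.86 to 0.90 and correlations of detection of 0.827 to 0.940. The median slope was 0.93 from 75 to 600 ng, 1.02 within slide row 1 and 0.92 with slide row as a block. It was lower with the background treatment, at 0.81 after normexp and 0.85 without background subtraction. Under those settings 11513 and 11471 probes departed from proportionality. Probes at or above the median of mean signal, a smaller set, gave 6643 rising, 6195 departing from proportionality and 4227 with a relative trend. Slide row as a block, which costs a degree of freedom and overlaps with amount, gave 2138 departing and 2650 with a relative trend. Leaving out 1 array gave 11526 to 11528, 8513 to 11312 and 5482 to 6752. Curvature gave 4944 after normexp, 2956 without background subtraction, 356 over all probes, 948 after scaling, 0 without moderation and 417 to 651 with 1 array left out; the cause was not tested. The power law share was 91.9% after normexp, 72.2% in that smaller set, and 20.8% to 96.0% with 1 array left out. Saturated probes stayed at 0; the alternative saturation limit and the gene list tests were not run. The median signal slope, the correlation of detection and the relative slopes of the named probes kept their signs under these alternatives, but balances did not. Bends turned from mostly down to mostly up after normexp, without background subtraction and without the 75 ng array. Relative trends turned from mostly steeper to mostly shallower after normexp, without background subtraction, with the row block (1168 and 1482) and with the percentile over all probes (3177 and 3385). The power law lost its majority without the 4800 ng array. CUST_978_PI425378893 missed the threshold under 10 of 17 alternatives and CUST_4040_PI425378893 under 1 of 16. Signal near background limits the dimmest probes.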

Other observations

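The tests of scanner saturation, binding ceilings, a fixed added signal, GC content, slide row, single raised spots, folding at 37 °C, the E1A deviations and the refits of shallow probes were chosen only after the results were seen.

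Some spots were raised on 1 array alone, by over 0.75 on the log2 scale against the mean of the neighbouring amounts. There were 449 such spots over the 5 inner arrays and 145 lowered by as much. The raised spots, 0.524% to 0.684% of those tested per array, were dim, with a median mean log2 signal of 3.59 to 4.78 by array. Their median distance to the nearest raised spot was on average 0.594 of that of random spots (permutation p = 0.0001, the smallest that 10000 draws give). Of 93 probes with 2 spots and at least 1 raised, both were raised in 3, or 3.23%.

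The probes with a slope under 0.5 numbered 259 on the processed signal, 127 bright and 132 dimmer, and the dimmer set depended on background treatment, at 1380 after normexp and 518 without subtraction. Scanner saturation is argued against, since their brightest spot reached 65.2% of the saturation value and 0 spots were marked. The bright ones had a mean log2 signal of 14 or more and numbered 127 under each treatment. For them a ceiling of the probe's own binding sites is a candidate explanation. The Langmuir curve was closer for 97.6% of them (exact interval 93.3 to 99.5), and for 72.4% to 99.2% with 1 array left out. The intervals given here and below count probes as independent, but all probes share the same arrays and their deviations. For all probes the interval was 21.8 to 23.3, while the Langmuir share ran from 4.03% to 79.2% with 1 array left out. These intervals are therefore too narrow, and the shares with 1 array left out show more of the uncertainty. For the 132 dimmer ones as a set a ceiling is argued against: the Langmuir share was 25.8% (18.5 to 34.1) where all probes had 22.6%, 15.9% without the 75 ng array (all probes 4.03%) and 43.9% (35.3 to 52.8) without the 4800 ng array (all probes 79.2%); it was 22.7% after normexp (all probes 8.06%) and 23.5% without subtraction (all probes 9.56%), so a ceiling in some of them stays possible. A fixed signal added at every amount stayed open for them too, since 56.1% bent upwards relative to the array and the interval, 47.2 to 64.7, included 50; no biological explanation was tested.

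Slopes that differ between probes went with sequence. GC content is a candidate explanation for a part of it, with a rank correlation of -0.209 at fixed mean signal, and -0.158 after normexp. For folding of the probe on itself, the prediction was that tighter folds have shallower slopes. That direction is argued against: at fixed mean signal and GC the correlation of folding energy with slope was -0.115 at 65 °C and -0.204 at 37 °C, opposite in sign to the prediction. With nothing held fixed it was 0.0233 (permutation p = 0.0126, adjusted 0.0126 over 5 relations), of the predicted sign but under the 0.1 that was asked for. An effect of folding in the other direction was not predicted, so folding as such was not excluded. Other properties of sequence stayed open, and no biological explanation was tested.

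The uneven steps between arrays were not explained. Within slide row 2 a later step exceeded an earlier one by 0.267 on the log2 scale, which slide row alone would not give, but the scatter of the medians gives such differences an SD of 0.273, so slide row stayed open. A scanning or washing effect that includes control oligos cannot be told apart from other sources with 7 arrays. The controls used also rose with amount themselves, so deviations shared with the probes would not single out scanning or washing. The deviations of the bright corners correlated with those of the probes at r = 0.568 (exact permutation p = 0.19; rho = 0.429, exact permutation p = 0.354), and those of the E1A spike-ins at r = 0.73 (exact permutation p = 0.0663; rho = 0.857, exact permutation p = 0.0238). No biological explanation was tested.

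Reordering the amounts showed which counts chance can give. For rising probes, 1 of 100 orders, the real one, gave 11528, and the highest other gave 11276. For relative trends, 1 of 100 gave 6743, and the highest other gave 2298. Neither count was matched by another drawn order, and 1 of 100 was the smallest share possible. The real order of amounts also followed slide position, so a trend with position was not excluded. For curvature, 11 of 100 orders gave at least 551 and the highest gave 11485, but a wrong order turns the overall rise of signal into a bend, so this decided nothing. Simulations without bends, with array-wide deviations of the observed size drawn independently for each array, gave a median of 34 probes, and 1 of 100 reached 551.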
